A study of Mus musculus with 15 samples.

How the data were processed

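The values deposited by the authors were gene counts, in 1 table of 22798 gene symbols and 15 libraries, with 0 columns left without a sample and 0 lines that stand for reads outside genes. Per the submitters' processing notes, Trimmomatic 0.30, HISAT2 2.0.1, HTSeq 0.6.1 and the genome build GRCm38 were used. The strand setting of the counting was not given in the sources used here. Libraries were checked for being copies of each other, and the lowest chi-square per degree of freedom between 2 libraries of 1 group was 78.1 (sedentary 4 and 5). Copies with counting noise alone would give about 1 if each count were a single read. In all 15 libraries, however, values of 4, 8 and 12 made up 32.1 to 50.2% of the values from 1 to 15. The deposited values may therefore not be plain counts of single reads, and why was not tested.

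Counts were filtered with filterByExpr, which left 17975 genes, scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood fit of all 15 libraries, robust dispersion and a prior count of 2 for log2-cpm. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors were taken from the fold change and its quasi-likelihood F statistic. Gene lists fixed in advance, of at least 5 members, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 44 lists tested. The exact permutation test of Cd47 took all ways to choose 3 of 9 libraries.

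Genes named in the text followed a rule: the 6 largest changes in each direction past the threshold at a mean log2-cpm of at least 1, passing over clone or model names and sex-linked genes, or the 3 smallest p-values in each direction where none passed, up to 4 members with the smallest p-values of each list that passed and of 9 lists in any case, and Cd47. This rule, the lists, the groups, the tests and the first set of alternatives were chosen before the data were examined. Symbols were matched to an annotation of GRCm38, with 22724 symbols found once, 48 several times and 26 not at all, for GC content, length and place.

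The GC correction took each library's log2-cpm less the mean of all libraries, fitted a lowess curve (span 0.3) on transcript GC content and used it as an offset in the same edgeR fit. It was added after the fold changes were seen to follow GC content, as were a correction for GC content and length, fits with the sets of numbers 1 to 3 and 4 to 6 as a block or alone, a fit without sedentary libraries 1 and 6, and a fit without the 2 abundant clone symbols. Alternatives planned at the start were RLE factors, DESeq2 1.42.0, limma-voom, other filters on low counts, only the groups compared, a fit without robust dispersion, the replicate number as a block, and leaving out each library in turn. The replicate numbers were checked as pairs: the correlations of exercise and sedentary libraries of the same number, within group means, were 0.194 to 0.364, while those of the same set and another number had a median of 0.265.

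The methods were tested on simulated data built on these counts. Of 100 genes changed by a log2 fold change of 1 or 2, edgeR recovered 30 and 86 for exercise against sedentary (6 false calls among 17344 genes), 17 and 91 for CD47-KO against sedentary (8 false calls among 17209) and 19 and 71 for CD47-KO against exercise (5 false calls among 17255). With a GC trend added to CD47-KO against sedentary, edgeR made 2046 false calls among 17347 genes, and 3 with the GC correction, which recovered 19 and 84. The added trend was a smooth function of the same GC content, alike in all CD47-KO libraries and at all lengths. This step therefore cannot show how well the correction removes the trend of the real libraries. In the simulations without a GC trend a list was also shifted by a log2 fold change of 0.5. It passed in each comparison, with 0 other lists called. Any of its members that were called count among the false calls given for those simulations. The simulated genes were drawn independently, so this step cannot show how often lists of correlated genes pass without a change. Over other groupings of the real libraries, the median number of lists called was 14 for exercise against sedentary and 12 for each CD47-KO comparison.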

Results

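The data were gene counts from RNA sequencing of skeletal muscle of C57BL/6 mice aged 12 months, taken after a night without food. There were 6 libraries from sedentary wild-type mice, 6 from mice that had exercised and 3 from mice labelled CD47-KO, the knockout of the thrombospondin 1 receptor CD47. Total counts ranged from 50928458 to 70774311 in the sedentary libraries, from 54851831 to 77628546 in the exercise libraries and from 76005277 to 84364189 in the libraries labelled CD47-KO. Mitochondrially encoded genes took 4.77 to 18.2% of the counts in sedentary, 4.49 to 12.5% in exercise and 18.1 to 19.2% in CD47-KO libraries. A pair of gene symbols named only for cloned sequences took 2.83 to 10.1% of the counts in sedentary and 0.880 to 12.3% in exercise libraries, but 0.0327 to 0.0596% in the CD47-KO libraries. Levels are in CPM (library-scaled counts), as mean ± SD over 6 sedentary, 6 exercise and 3 CD47-KO libraries, and fold changes are log2 values with their standard error (SE).

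The first principal component of all 15 libraries, with 23.6% of the variance, separated numbers 1 to 3 of the exercise and sedentary groups from numbers 4 to 6 of both. The second, with 19.0%, separated the 3 libraries labelled CD47-KO. No label names these sets of numbers. In the sample descriptions, exercise libraries 4 to 6 carry other numbers than in their titles, so pairs and blocks by number rest on the titles. The CD47-KO libraries lay apart from both sets, so a batch of their own and their group cannot be told apart. The labels do not state that the libraries come from separate animals, so the p-values measure the spread between these libraries only, whatever its source. Across exercise and sedentary libraries, 2486 genes were higher and 2408 lower in numbers 1 to 3 than in numbers 4 to 6, of 15571 tested.

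**Figure D1:**
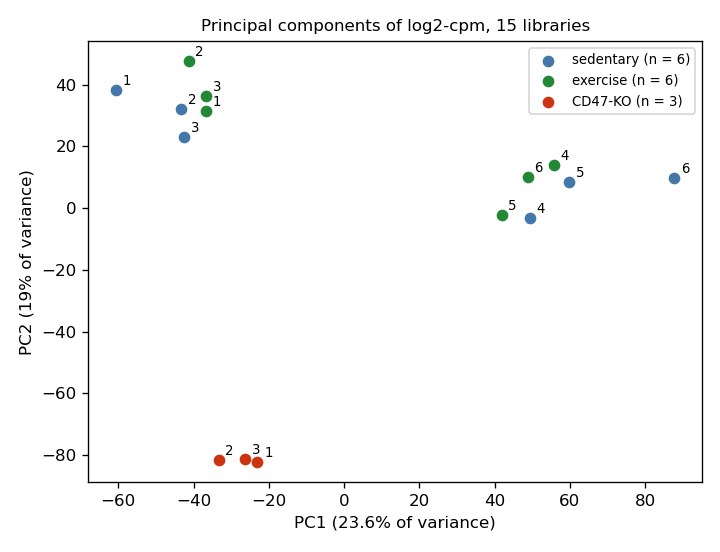
First and second principal components of log2-cpm in 15 libraries, with each point 1 library, its number beside it and its group in colour. Numbers 1 to 3 and 4 to 6 of the sedentary and exercise groups lie apart along the first component (23.6% of the variance), and the 3 CD47-KO libraries lie apart along the second (19.0%).

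Cd47, on chromosome 16 from 49800533 to 49915010 of GRCm38, was measured in every library. Its level was 11.5, 12.1 and 12.1 CPM in libraries 1 to 3 labelled CD47-KO. It was 16.4, 13.98, 11.4, 13.9, 14.04 and 15.9 CPM in sedentary libraries 1 to 6 and 10.8, 13.4, 11.8, 14.3, 15.7 and 14.3 CPM in exercise libraries 1 to 6. The means were 11.9 ± 0.356 (SD, n = 3) for CD47-KO, 14.3 ± 1.77 (SD, n = 6) for sedentary and 13.4 ± 1.81 (SD, n = 6) for exercise. Against sedentary, the log2 fold change of the libraries labelled CD47-KO was -0.26 (SE 0.17), with an adjusted p of 0.295 by edgeR's quasi-likelihood test. The exact two-sided permutation test over 84 arrangements gave p = 0.0833, where 0.0119 is the smallest it can give. Cd47 was therefore not lower by the test, and the group is called "the libraries labelled CD47-KO" or CD47-KO, as a label. A correction for GC content moved the log2 fold change to -1.21 (adjusted p = 0.00274).

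**Figure D2:**
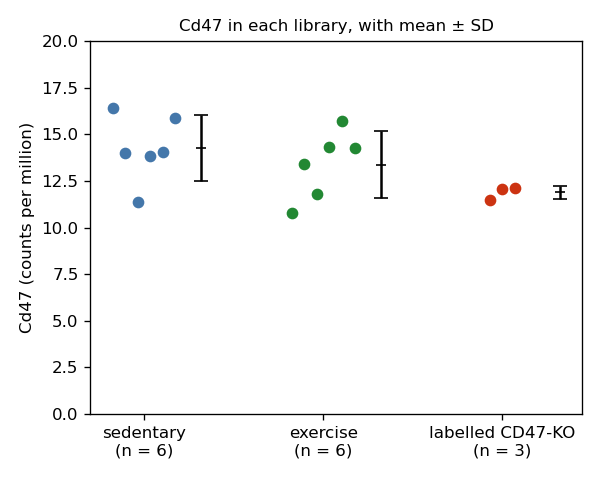
Cd47 in CPM in each library, with the group mean ± SD in black. The 3 libraries labelled CD47-KO lie at 11.5 to 12.1 CPM, within the range of the 6 sedentary libraries.

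Exercise was set beside sedentary to ask what exercise changed in fasted muscle. Exercised muscle differed in lists of genes, by a set test with a preset correlation between genes, and not in single genes by edgeR, where DESeq2 called 9 and edgeR with the set of numbers as a block called 1 (Il15, 1.38). Of 100 groupings of the libraries, the real one among them, however, 44 gave at least the 15 lists called (highest other 21), so their number is no larger than other groupings gave. The enzymes of the tricarboxylic acid cycle, which oxidise acetyl-CoA in mitochondria, rose as a list, with 20 of 21 members above 0 and a median log2 fold change of 0.34 (adjusted p = 2.00e-08 by camera, adjusted p = 0.770 with an estimated correlation). The fatty acid oxidation list rose with 30 of 31 members above 0 and a median of 0.38 (adjusted p = 2.64e-08, adjusted p = 0.770 with an estimated correlation). Branched-chain amino acid and ketone metabolism rose with 19 of 20 members above 0 and a median of 0.35 (adjusted p = 9.10e-08, adjusted p = 0.770 with an estimated correlation). The slow fibre list, the contractile genes of oxidative fibres, fell with 2 of 18 members above 0 and a median of -1.49 (adjusted p = 6.19e-06, adjusted p = 0.770 with an estimated correlation).

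Members of these lists are given as values, since no gene passed on its own in the edgeR test. Suclg2, a subunit of succinyl-CoA ligase, had a log2 fold change of 0.67 (SE 0.22) and 57.1 ± 16.3 against 35.9 ± 8.97 CPM. Sdha, the catalytic subunit of succinate dehydrogenase, had 0.49 (SE 0.20). In fatty acid oxidation, Cpt2, which reforms acyl-CoA inside mitochondria, had 0.53 (SE 0.19), the short-chain dehydrogenase Acads 0.37 (SE 0.14) and the fatty acid transporter Cd36 0.45 (SE 0.32), or -0.13 with numbers 1 to 3 alone. Pcca, a subunit of propionyl-CoA carboxylase, had 0.40 (SE 0.14) and Bckdha, of the branched-chain keto acid dehydrogenase, 0.42 (SE 0.16). Within numbers 1 to 3 and within numbers 4 to 6, the list medians were 0.14 and 0.49 for the tricarboxylic acid cycle, -0.09 and 0.71 for fatty acid oxidation and 0.10 and 0.47 for branched-chain and ketone metabolism. The respiratory chain lists did not pass: complex I had a median of -0.01 (adjusted p = 0.292), with 0.31 (SE 0.14) for Ndufa10, and complexes II to IV had 0.04 (adjusted p = 0.120), with 0.29 (SE 0.15) for Uqcrc1. The AMPK pathway list had a median of 0.09 (adjusted p = 0.0529), with 0.26 (SE 0.15) for the kinase adaptor Stradb and 0.30 (SE 0.20) for the acetyl-CoA carboxylase Acacb.

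Among the fibre genes, troponin Tnnt1 had -1.85 (SE 0.88) and 173 ± 105 against 625 ± 796 CPM, tropomyosin Tpm3 -1.59 (SE 0.69) and the muscle LIM protein Csrp3 -1.73 (SE 0.75). Sedentary library 1 held Myh7, the slow myosin heavy chain and a gene chosen after its values were seen, at 9789.6 CPM and exercise library 3 at 7.85 CPM. The slow fibre medians within numbers 1 to 3 and 4 to 6 were -1.84 and -0.33, and the median was -0.65 without sedentary library 1. The fast fibre list did not pass (median 0.05, adjusted p = 0.09999). Myh1, the heavy chain of fast oxidative-glycolytic fibres, had 1.20 (SE 0.29) with 4972 ± 2045 against 2164 ± 705 CPM and was the 1 fast fibre member that passed when adjusted over the list alone.

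The fasting and atrophy list, with FoxO targets and ubiquitin ligases, also rose (23 of 30 members above 0, median 0.22, adjusted p = 0.000358, adjusted p = 0.770 with an estimated correlation). Its members had 0.60 (SE 0.27) for Gadd45a, 0.43 (SE 0.22) for Cebpb and 0.31 (SE 0.18) for Foxo4. Glycolysis and glycogen rose with a median of 0.08 (adjusted p = 0.00987, adjusted p = 0.832 with an estimated correlation), which was -0.02 without sedentary library 1. Values were 0.48 (SE 0.20) for Pfkfb1, 0.46 (SE 0.22) for the glycogen synthase Gys1 and 0.31 (SE 0.19) for Pfkm. Regulators of mitochondrial biogenesis rose with a median of 0.15 (adjusted p = 0.0121, adjusted p = 0.770 with an estimated correlation), as in 0.36 (SE 0.17) for Sirt3 and 0.30 (SE 0.16) for Tfb2m. Immediate early genes rose with a median of 0.30 (adjusted p = 0.00368, adjusted p = 0.832 with an estimated correlation). Among them were 1.70 (SE 0.65) for Junb, 1.31 (SE 0.59) for Maff and 0.82 (SE 0.43) for Nr4a1. Junb had -0.62 with numbers 4 to 6 alone, and the list medians within numbers 1 to 3 and 4 to 6 were 0.41 and 0.15, the latter with adjusted p = 0.176. Autophagy rose (median 0.11, 0.25 (SE 0.16) for Map1lc3b, adjusted p = 0.0363, adjusted p = 0.832 with an estimated correlation). The clock list rose (median 0.20, 0.28 (SE 0.24) for Per2, adjusted p = 0.0447, adjusted p = 0.770 with an estimated correlation). Cellular senescence rose (median 0.07, 0.37 (SE 0.26) for Cdkn1a, adjusted p = 0.0447, adjusted p = 0.770 with an estimated correlation). Gadd45b, with 1.37 (SE 0.34), was the 1 senescence member that passed when adjusted over the list alone. Cytosolic ribosomal proteins fell with 2 of 70 members above 0 and a median of -0.30 (adjusted p = 3.73e-05, adjusted p = 0.911 with an estimated correlation).

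Markers of other cell types passed the set test as well. Macrophage markers rose (median 0.20, 0.58 (SE 0.43) for Mrc1, adjusted p = 0.0296, adjusted p = 0.911 with an estimated correlation). Schwann cell and nerve markers fell (median -0.54, -1.29 (SE 0.48) for S100b, adjusted p = 0.0360, adjusted p = 0.832 with an estimated correlation). Tendon and cartilage markers fell (median -0.74, -0.85 (SE 0.33) for the tendon factor Scx, adjusted p = 0.0328, adjusted p = 0.911 with an estimated correlation), with a direction that rested on sedentary library 1 (median 0.44 without it).

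No single gene of 17975 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 665 had an unadjusted p under 0.05, or 1045 with the replicate number as a block, where 899 would by chance. limma-voom called 0 and DESeq2 called 9 genes, 2 higher and 7 lower, with Alb, Ahsg and Serpina3k among those lower. The smallest p-values upwards belonged to the peptidylarginine deiminase Padi2 (0.82, SE 0.17, 146 ± 25.9 against 83.1 ± 18.6 CPM, higher in 6 of 6 libraries than in any sedentary library). Next came Gm15564 (13.5 ± 16.5 against 0.0242 ± 0.0526 CPM) and the Wnt antagonist Frzb (1.46, SE 0.31). In the other direction they belonged to Gm14391, at 0.161 ± 0.0614 CPM in sedentary and 0 counts in all exercise libraries (adjusted p = 0.0996), the serum protein gene Alb, at 4.79 ± 5.44 CPM in sedentary and 0 counts in all exercise libraries, and the deadenylase Cnot7 (-1.06, SE 0.23). Over all genes tested 0 members of any list passed, and adjusted over the list alone 1 passed in each of the fast fibre, cellular senescence and myokine lists and 0 in the other lists. With an estimated correlation 0 of the 15 lists called (11 higher, 4 lower, of 44) passed, and fry called 0 (lowest adjusted p = 0.762). Leaving out sedentary libraries 1 and 6, whose scaling factors lay farthest from 1, kept 7 of the 15 calls. There the fasting list had adjusted p = 0.0708, and the ribosomal and tendon lists turned their direction. Leaving out 1 library at a time never ended the calls of the tricarboxylic acid cycle, fatty acid oxidation, branched-chain and ketone metabolism, fasting and slow fibre lists. With numbers 1 to 3 alone, however, 9 of the 15 calls were kept, and fatty acid oxidation turned its direction (adjusted p = 0.459). With numbers 4 to 6 alone 6 were kept, and slow fibre had adjusted p = 0.483. The ribosomal list turned its direction without sedentary library 6 (adjusted p = 0.128), biogenesis regulators had adjusted p = 0.162 without that library and glycolysis 0.599 without sedentary library 1 and 0.0883 without exercise library 3. The other 7 lists that lost their calls had their highest adjusted p without sedentary library 1 (autophagy 0.266, tendon 0.865) or sedentary library 2 (Schwann cell 0.381). For others it was without sedentary library 3 (macrophage 0.542), exercise library 3 (senescence 0.311) and sedentary library 6 (clock 0.430), and immediate early genes had 0.0951 without exercise library 2. Over the 12 fits that left out 1 library, the medians ran from 0.24 to 0.44 for the tricarboxylic acid cycle, 0.25 to 0.47 for fatty acid oxidation, 0.25 to 0.41 for branched-chain and ketone metabolism, -1.75 to -0.65 for slow fibre, 0.13 to 0.29 for fasting, 0.10 to 0.22 for biogenesis regulators and 0.06 to 0.16 for autophagy. They ran from 0.19 to 0.61 for immediate early genes, 0.03 to 0.24 for the clock and -0.75 to -0.22 for Schwann cell markers. The medians changed sign for glycolysis (-0.02 to 0.13), macrophage (-0.07 to 0.46), tendon (-1.31 to 0.44), senescence (-0.01 to 0.26) and ribosomal proteins (-0.39 to 0.05).

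The libraries labelled CD47-KO were set beside sedentary to ask what the loss of CD47 changes in muscle, and Cd47 itself was not lower in them by the test. They differed from the 6 sedentary libraries in 3719 of 17975 genes, 2146 higher and 1573 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes of the fasting and atrophy response rose: 14 of 30 members were higher and 1 lower, among them the pyruvate dehydrogenase kinase Pdk4 at 5059 ± 850.4 against 1429 ± 502 CPM. Nuclear genes of oxidative phosphorylation and ribosomal protein genes fell, with 17 of 36 complex I genes and 38 of 70 ribosomal protein genes lower, or 9 and 21 after a correction for GC content. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.939. Several fast fibre genes fell too, such as the myosin light chain Mylpf at 3547 ± 324 against 10584 ± 2647 CPM. Myh1, added here after its values were seen, lay the other way as the 1 member of 22 above 0. It had 4461, 4818 and 3678 CPM in CD47-KO libraries 1 to 3, against 1232 to 2925 CPM in sedentary, but did not pass over all genes tested.

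The fold changes followed GC content. Across 10725 expressed genes, which are not independent replicates, the Spearman correlation of the log2 fold change with transcript GC content was -0.651 against sedentary, while it was 0.0294 for exercise against sedentary. The median log2 fold change was 1.29 in the decile of genes lowest in GC content and -0.58 in the highest decile. The genes called higher had a median GC content of 42.5% and those called lower 54.7%, against 49.7% of all genes tested. After correction for this trend, 1748 genes passed (850 higher, 898 lower), and 1175 of the 3719 kept their call and direction. GC-corrected counts of list members are therefore given beside those as tested.

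**Figure D3:**
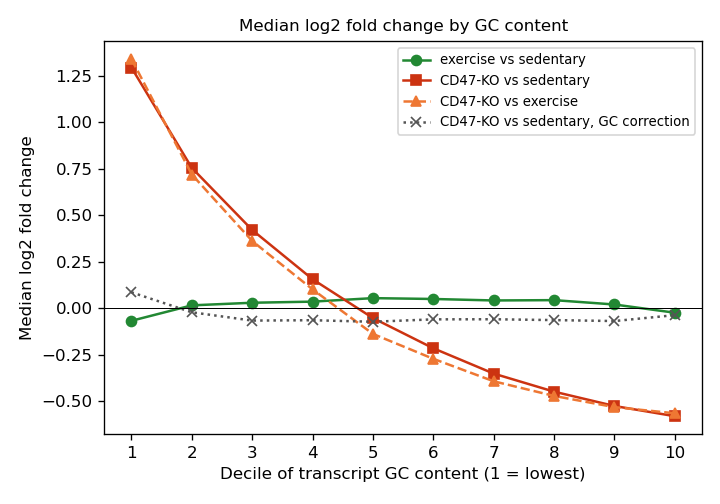
Median log2 fold change of expressed genes in each decile of transcript GC content, for the 3 comparisons and for CD47-KO against sedentary after the GC correction. The median of CD47-KO against sedentary falls from 1.29 in the lowest decile to -0.58 in the highest, and exercise against sedentary stays between -0.07 and 0.05.

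The largest increases were those of Tmed5, which sorts cargo in the secretory pathway (3.87, SE 0.49, 90.8 ± 30.6 against 6.20 ± 3.15 CPM, adjusted p = 8.18e-05), and the scaffold gene Erbin (3.72, SE 0.55). They were followed by Trdn, which anchors the calcium release complex (3.61, SE 0.45, 1607 ± 163 against 132 ± 75.4 CPM), the transcription factor Sp4 (3.56, SE 0.38), Esf1 (3.41, SE 0.26) and the splicing regulator Mbnl1 (3.41, SE 0.64). After the GC correction these 6 had log2 fold changes of 2.14 to 2.59, and all stayed past the threshold. The largest decreases were those of the small structural RNAs Rn7s1 (-6.52, SE 0.96, 2.29 ± 0.318 against 211 ± 151 CPM), Rn7s2 (-5.79, SE 1.14) and Rn7sk (-5.10, SE 0.92). Next were the nephrin gene Nphs1 (-3.52, SE 0.83), the ribosomal protein gene Rps29 (-3.01, SE 0.56) and the clock output gene Dbp (-2.98, SE 0.48, 4.78 ± 0.882 against 37.8 ± 25.2 CPM). These 6 also stayed past the threshold after the GC correction. Rn7s1 and Rn7s2 are near-identical copies, and ribosomal protein genes have many processed copies, so the split of reads between copies is uncertain. The 2 clone symbols also took only 0.0327 to 0.0596% of the counts in these 3 libraries. Whether the falls of Rn7s1, Rn7s2 and Rn7sk come from how the libraries were made or from the group cannot be told apart.

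The fasting and atrophy list passed the set test upwards (adjusted p = 0.000334 by camera, adjusted p = 0.939 with an estimated correlation), with a median of 0.88; 14 and 1 members were higher and lower when adjusted over the list alone. Sesn1, a stress-induced inhibitor of mTORC1, had 2.49 (SE 0.32) (adjusted p = 9.87e-05), Gadd45a 2.37 (SE 0.31), the lysosomal protease Ctsl 1.54 (SE 0.20) and the ubiquitin ligase Fbxo30 2.89 (SE 0.44). After the GC correction the list median was 1.07, with 13 members higher and 1 lower, and these 4 genes had 2.56, 2.43, 0.95 and 1.61. The fry test, which asks whether the members move on balance in 1 direction, called this list alone of 44 (adjusted p = 0.000860).

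**Figure D4:**
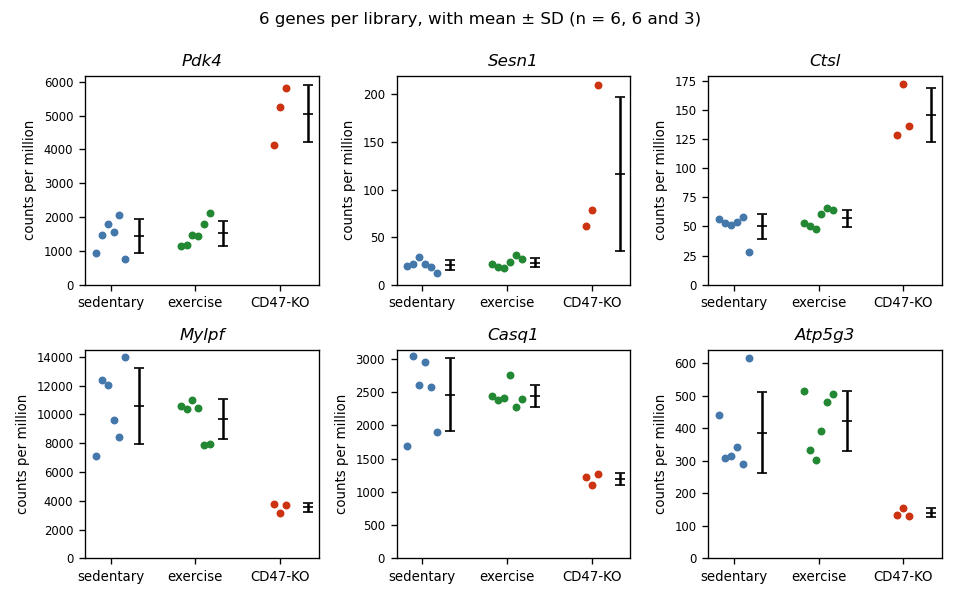
Level in CPM of Pdk4, Sesn1, Ctsl, Mylpf, Casq1 and Atp5g3 in each library, with group mean ± SD in black, on axes that start at 0. In the 3 CD47-KO libraries Pdk4 lies at 5059 ± 850.4 and Mylpf at 3547 ± 324 CPM, against 1429 ± 502 and 10584 ± 2647 CPM in the 6 sedentary libraries.

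Among the nuclear genes of oxidative phosphorylation, the complex I list fell with a median of -0.97 (adjusted p = 3.24e-08, adjusted p = 0.939 with an estimated correlation). Of its 36 members 0 rose and 17 fell, and 1 and 24 when adjusted over the list alone. Complexes II to IV fell with a median of -0.72 (adjusted p = 0.00473, adjusted p = 0.939 with an estimated correlation). Of its 26 members 1 rose and 6 fell, and 1 and 9 when adjusted over the list alone. The ATP synthase list fell with a median of -0.85 (adjusted p = 0.000462, adjusted p = 0.939 with an estimated correlation). Of its 15 members 0 rose and 7 fell, and 0 and 7 when adjusted over the list alone. With the replicate number as a block, complexes II to IV and ATP synthase lost their calls. Ndufb6 had -1.41 (SE 0.30), Ndufv1 -0.87 (SE 0.20), Ndufa8 -1.44 (SE 0.33), Cox4i1 -1.34 (SE 0.32), Cox7a2 -1.59 (SE 0.40), Cox8b -2.33 (SE 0.61), Atp5g3 -1.46 (SE 0.27), Atp5g1 -1.26 (SE 0.31) and Atp5k -2.36 (SE 0.59), the Atp5g genes being paralogs. After the GC correction the medians were -0.90, -0.71 and -0.80, with 0 members higher in each and 9, 2 and 5 lower. With a correction for GC content and length they were -0.56, -0.25 and -0.54, with 1, 1 and 0 members higher and 12, 3 and 5 lower. Ndufb6, Atp5g3, Atp5g1 and Atp5k stayed past the threshold and the other 5 genes did not. Ndufv1 did not pass without CD47-KO library 3 (-0.76), Cox7a2 without CD47-KO library 1 (-1.45) or CD47-KO library 3 (-1.51), Cox8b without CD47-KO library 1 (-2.23) or CD47-KO library 3 (-2.21), Atp5g1 without CD47-KO library 1 (-1.19) or CD47-KO library 3 (-1.15) and Atp5k without CD47-KO library 1 (-2.21). The median of the 76 nuclear genes together, -0.89, lay below all 10000 random lists matched on GC content, length and level, 95% of which had medians from -0.63 to -0.29. Each random list was drawn gene by gene, so this spread leaves out the correlation between members of a real list. It therefore cannot show how rare such a median is for correlated genes.

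Some of these lists also differed between the unnamed sets of numbers. Among the other 12 libraries, numbers 1 to 3 less numbers 4 to 6 had medians of -0.71 (28 of 36 lower) for complex I, -0.81 (20 of 26 lower) for complexes II to IV, -0.50 (8 of 15 lower) for ATP synthase, -0.70 (43 of 70 lower) for ribosomal proteins and -1.03 (12 of 15 lower) for the mitochondrially encoded list. The 3 libraries labelled CD47-KO lay at -33.3 to -23.0 on the first component, on the side of numbers 1 to 3. Against the sedentary libraries of numbers 1 to 3 alone, complex I (adjusted p = 0.000732) and ribosomal proteins (7.79e-06) kept their calls, and complexes II to IV (0.456) and ATP synthase (0.0768) did not.

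The mitochondrially encoded list rose instead, with a median of 1.32 (adjusted p = 0.00162, adjusted p = 0.939 with an estimated correlation). Of its 15 members 6 rose and 0 fell, and 9 and 1 when adjusted over the list alone. mt-Nd4l had 2.37 (SE 0.36), mt-Nd5 2.14 (SE 0.39), mt-Atp8 2.06 (SE 0.36) and mt-Nd6 1.57 (SE 0.40). These genes have a median GC content of 36.0%, and after the GC correction the list had a median of -0.11 and an adjusted p of 0.799, with mt-Nd4l the 1 member still higher and 2 members lower. With GC content and length the median was 0.41, with 2 members higher and 2 lower and adjusted p = 0.283. mt-Atp8 and mt-Nd4l overlap their neighbours and mt-Nd6 lies on the other strand, so their counts are uncertain where strand was not used.

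Cytosolic ribosomal proteins fell with a median of -1.08 (adjusted p = 1.95e-14, adjusted p = 0.939 with an estimated correlation). Of its 70 members 0 rose and 38 fell, and 0 and 50 when adjusted over the list alone. Rps28 had -2.47 (SE 0.43) and Rps3 -1.18 (SE 0.21), and after the GC correction the median was -0.95 with 21 members lower, and with GC content and length -0.60. The fast fibre list fell with a median of -0.67 (adjusted p = 0.000334, adjusted p = 0.939 with an estimated correlation). Of its 22 members 0 rose and 6 fell, and 1 and 8 when adjusted over the list alone. Mylpf had -1.58 (SE 0.25), the calcium store protein Casq1 -1.04 (SE 0.22) and creatine kinase Ckm -0.92 (SE 0.26). GC-corrected, they had -1.31, -0.82 and -0.59, the last with adjusted p = 0.183. Ckm did not pass without CD47-KO library 1 (-0.99), CD47-KO library 2 (-0.83) or CD47-KO library 3 (-0.91). With the GC correction 1 and 3 fast fibre members were higher and lower, and with GC content and length the list had a median of -0.23 and adjusted p = 0.131. The slow fibre list did not pass (median -0.90, adjusted p = 0.409), with -1.68 (SE 0.74) for Myl6b and -1.36 (SE 1.02) for Tnni1. Glycolysis and glycogen fell with a median of -0.49 (adjusted p = 0.0196, adjusted p = 0.939 with an estimated correlation). Of its 27 members 3 rose and 9 fell, and 4 and 12 when adjusted over the list alone. This list lost its call with the replicate number as a block. The enolase Eno3 had -1.08 (SE 0.24) and Pgam2 -1.29 (SE 0.31), while Ugp2, which makes UDP-glucose, had 1.06 (SE 0.26). After the GC correction 0 members passed, the list had adjusted p = 0.0608 and Ugp2 turned to -0.19. Set against matched random lists in the same way, the ribosomal list lay below all 10000 and the fasting list above all, glycolysis at percentile 0.620, fast fibre at 2.55, antigen presentation at 5.10 and, matched on GC content alone, the mitochondrially encoded list at 32.7. The limit given above for random lists drawn gene by gene holds here too.

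Other metabolic lists did not pass as sets but held changed genes. In fatty acid oxidation (median 0.39, adjusted p = 0.0678) 7 rose and 0 fell of 31, and 7 and 0 when adjusted over the list alone. Pdk4 had 1.82 (SE 0.29), the peroxisomal enzyme Ehhadh 1.87 (SE 0.30), lipoprotein lipase Lpl 2.17 (SE 0.42) and Cd36 1.94 (SE 0.38). GC-corrected, 6 and 0 members were higher and lower, Pdk4 (1.34) and Ehhadh (1.64) stayed past the threshold, and Lpl (1.38, adjusted p = 0.0693) and Cd36 (0.57, adjusted p = 0.295) did not. Among regulators of mitochondrial biogenesis (adjusted p = 0.358) 7 rose and 1 fell of 24, and 7 and 1 when adjusted over the list alone. Gabpa had 2.35 (SE 0.27), the deacetylase Sirt1 1.81 (SE 0.34), Esrrg 1.71 (SE 0.35) and Tfb2m 1.18 (SE 0.19). GC-corrected, 3 and 1 members were higher and lower, Gabpa (1.37) and Sirt1 (1.21) passed and Esrrg (0.82) and Tfb2m (0.33) did not. In the AMPK pathway (adjusted p = 0.765) 6 rose and 2 fell of 24, and 6 and 2 when adjusted over the list alone. Cab39 had 1.52 (SE 0.23), its partner Stradb -0.78 (SE 0.19) and the AMPK-binding Fnip1 1.62 (SE 0.30). GC-corrected, they had 1.06, -1.66 and 0.33, where Fnip1 did not pass and 3 and 2 members of the list were higher and lower. In the list of CD47, thrombospondin and nitric oxide signalling (adjusted p = 0.358) 8 rose and 3 fell of 23, and 9 and 3 when adjusted over the list alone. The integrin Itgav had 2.19 (SE 0.50), Ubqln1 0.86 (SE 0.17) and caveolin Cav3 -1.04 (SE 0.25). GC-corrected, they had 1.55, 0.73 and -0.58, where Cav3 did not pass and 2 and 2 members were higher and lower. Stradb did not pass without CD47-KO library 1 (-0.71) and Cav3 without CD47-KO library 3 (-0.96).

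Among other cell types, the endothelial list fell (median -0.65, adjusted p = 0.00990, adjusted p = 0.939 with an estimated correlation). Of its 26 members 1 rose and 4 fell, and 1 and 4 when adjusted over the list alone, with -2.35 (SE 0.43) for Aplnr, -1.08 (SE 0.30) for Cldn5 and 1.93 (SE 0.35) for the vessel ligand Angpt1. The smooth muscle and pericyte list fell (median -0.76, adjusted p = 0.0196, adjusted p = 0.939 with an estimated correlation). Of its 15 members 1 rose and 5 fell, and 2 and 7 when adjusted over the list alone, with -1.42 (SE 0.27) for Smtn, -1.19 (SE 0.33) for Acta2 and 1.59 (SE 0.33) for the pericyte gene Rgs5. The antigen presentation list fell (median -0.64, adjusted p = 0.00473, adjusted p = 0.939 with an estimated correlation). Of its 21 members 0 rose and 6 fell, and 0 and 7 when adjusted over the list alone, with -1.06 (SE 0.24) for H2-D1 and -0.75 (SE 0.23) for H2-T22, members of a multigene family whose reads are hard to tell apart. These 3 lists had adjusted p = 0.0876, 0.154 and 0.0876 after the GC correction, with 0, 0 and 0 members higher and 1, 2 and 1 lower. Cldn5, Angpt1, Rgs5, H2-D1 and H2-T22 did not pass. Cldn5 did not pass without CD47-KO library 3 (-0.84), Acta2 without CD47-KO library 1 (-1.21) or CD47-KO library 3 (-0.96) and H2-T22 without sedentary library 4 (-0.69), sedentary library 5 (-0.67), sedentary library 6 (-0.62), CD47-KO library 1 (-0.75), CD47-KO library 2 (-0.74) or CD47-KO library 3 (-0.70).

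**Figure D5:**
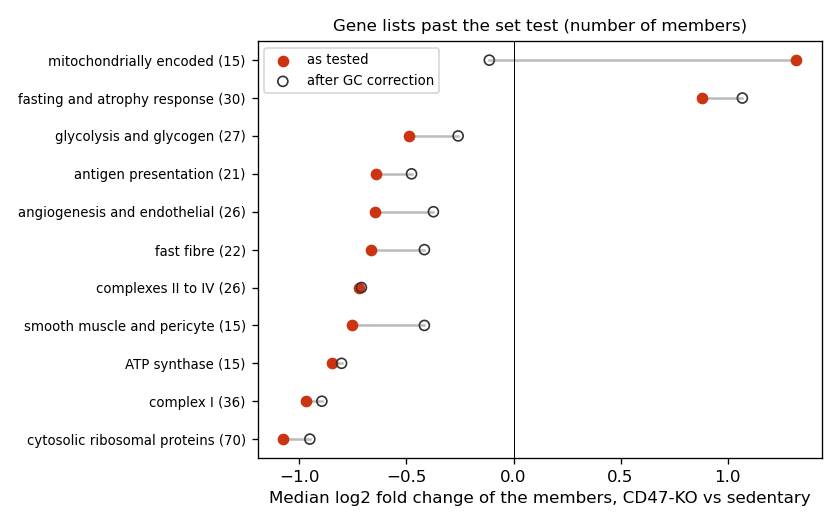
Median log2 fold change of the members of the 11 lists that passed the set test in CD47-KO against sedentary, as tested (filled) and after the GC correction (open), with the number of members in brackets. The fasting and atrophy list lies at 0.88 and 1.07, and the mitochondrially encoded list moves from 1.32 to -0.11.

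Of the 11 lists (2 higher, 9 lower, of 44), 0 passed with an estimated correlation and 6 kept their call after the GC correction. Leaving out 1 library ended the call of the endothelial list (without sedentary library 6, adjusted p = 0.0920) and the smooth muscle list (without sedentary library 6, 0.0622). It also ended that of glycolysis (without sedentary library 3, sedentary library 4 or CD47-KO library 2, 0.0560, 0.0559 and 0.102). No list median changed sign when 1 library was left out, but without sedentary library 6 it moved to -0.65 for complex I, -0.42 for complexes II to IV, -0.38 for ATP synthase, -0.66 for ribosomal proteins and 2.004 for the mitochondrially encoded list. With the sedentary libraries of numbers 1 to 3 alone, adjusted p was 0.0619 for fast fibre, 0.176 for glycolysis and 0.0608 for smooth muscle. With those of numbers 4 to 6 alone it was 0.130 for the mitochondrially encoded list, 0.123 for endothelial, 0.0533 for antigen presentation and 0.0973 for smooth muscle. The count of genes was 2361 (1718 higher, 643 lower), 2245 (1452 and 793) and 2178 (1580 and 598) without CD47-KO library 1, 2 and 3, so that the number lower shrank more than the number higher. With only the groups compared it was 2647 (1912 and 735). The count was 5588 and 4662 with the sedentary libraries of numbers 1 to 3 or 4 to 6 alone.

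Set beside exercise, the libraries labelled CD47-KO differed in 10 lists, all among the 11 that passed against sedentary. Both comparisons use the same 3 libraries, so like directions are no separate evidence. With an estimated correlation 0 of these lists passed (lowest adjusted p = 0.953). The libraries differed in 3698 of 17975 genes, 2198 higher and 1500 lower, and again Cd47 was not lower by the test (-0.17, SE 0.17, adjusted p = 0.518). After the GC correction, and after that for GC content and length, Cd47 did pass as lower than in exercise. 1849 genes were higher and 1147 lower both here and against sedentary, with the same limit. Sesn1 (2.32, SE 0.32), Fbxo30 (3.01, SE 0.44) and Pdk4 (1.73, SE 0.29, 5059 ± 850.4 against 1521 ± 374 CPM) were higher than in exercised muscle. Lower were 16 of 36 complex I, 8 of 26 complex II to IV, 8 of 22 fast fibre and 23 of 70 ribosomal protein genes, or 8, 3, 3 and 9 after the GC correction.

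Among the largest increases were those of Erbin (4.15, SE 0.56), Mbnl1 (4.13, SE 0.65), Tmed5 (4.06, SE 0.49), Trdn (4.03, SE 0.46) and Esf1 (3.82, SE 0.26), all past the threshold after the GC correction. Among the largest decreases were Rn7s1 (-5.86, SE 0.92), Rn7s2 (-5.50, SE 1.12), Rn7sk (-4.44, SE 0.89), Dbp (-3.44, SE 0.50) and Fam78a (-2.97, SE 0.42), which also stayed past it. The limits given above for Rn7s1, Rn7s2 and Rn7sk hold here too. Complex I fell with 16 of 36 members lower and 0 and 21 higher and lower when adjusted over the list alone (median -0.98, adjusted p = 5.38e-09, adjusted p = 0.953 with an estimated correlation). Values were -1.10 (SE 0.20) for Ndufv1 and -0.84 (SE 0.18) for Ndufa9. Complexes II to IV fell with 8 of 26 lower, 1 higher and 1 and 10 when adjusted over the list alone (median -0.81, adjusted p = 0.000883, adjusted p = 0.953 with an estimated correlation). Values were -0.99 (SE 0.19) for Uqcrc1 and -1.13 (SE 0.24) for Cyc1. The list of complexes II to IV lost its call with the replicate number as a block. ATP synthase genes fell with 6 of 15 lower and 0 and 8 when adjusted over the list alone (median -0.72, adjusted p = 0.000165, adjusted p = 0.953 with an estimated correlation). Values were -1.59 (SE 0.27) for Atp5g3. The mitochondrially encoded list rose with 7 of 15 higher and 10 and 0 when adjusted over the list alone (median 1.38, adjusted p = 0.00111, adjusted p = 0.953 with an estimated correlation). Values were 2.27 (SE 0.36) for mt-Nd4l and 2.09 (SE 0.39) for mt-Nd5. After the GC correction 8, 3 and 4 members of complex I, complexes II to IV and ATP synthase were lower and 0 higher, and with GC content and length the medians were -0.53, -0.44 and -0.34. The mitochondrially encoded list had 1 and 1 members higher and lower, a median of -0.18 (0.20 with GC content and length) and adjusted p = 0.399 after the GC correction.

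The fasting and atrophy list rose with 11 of 30 members higher, 1 lower and 12 and 1 when adjusted over the list alone (median 0.56, adjusted p = 0.0156, adjusted p = 0.953 with an estimated correlation). Fast fibre genes fell with 8 of 22 lower and 0 and 9 when adjusted over the list alone (median -0.66, adjusted p = 2.81e-05, adjusted p = 0.953 with an estimated correlation). Values were -1.45 (SE 0.25) for Mylpf and -1.03 (SE 0.22) for Casq1. The slow fibre list did not pass (median 0.55, adjusted p = 0.618). Glycolysis and glycogen fell with 10 of 27 lower, 1 higher and 4 and 15 when adjusted over the list alone (median -0.73, adjusted p = 0.00124, adjusted p = 0.953 with an estimated correlation). Values were -1.17 (SE 0.24) for Eno3, -0.95 (SE 0.23) for Gpi1 and -1.15 (SE 0.28) for Gys1, none of which passed after the GC correction. Gpi1 did not pass without CD47-KO library 1 (-0.87), Gys1 without CD47-KO library 1 (-1.04) and H2-T23 without CD47-KO library 1 (-0.74) or CD47-KO library 3 (-0.95). Ribosomal proteins fell with 23 of 70 lower and 0 and 32 when adjusted over the list alone (median -0.80, adjusted p = 1.15e-09, adjusted p = 0.953 with an estimated correlation). Values were -2.04 (SE 0.42) for Rps28 and -1.06 (SE 0.21) for Rps3. The endothelial list (median -0.45, adjusted p = 0.0386, adjusted p = 0.953 with an estimated correlation) fell as well, and so did antigen presentation (median -0.79, -0.94 (SE 0.28) for H2-T23, adjusted p = 0.00165, adjusted p = 0.953 with an estimated correlation). They had 5 and 5 members lower over all genes tested and 5 and 7 adjusted over the list alone. GC-corrected members higher and lower were 13 and 1 for fasting, 0 and 3 for fast fibre, 0 and 0 for glycolysis, 0 and 9 for ribosomal proteins, 0 and 1 for endothelial and 0 and 0 for antigen presentation. With GC content and length the medians of fast fibre and ribosomal proteins were -0.28 and -0.39.

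Fatty acid oxidation did not pass (adjusted p = 0.925; 5 rose and 1 fell of 31, and 5 and 1 when adjusted over the list alone), with -0.83 (SE 0.17) for Acads. After the GC correction Acads (-0.29), Cyc1 (-0.57), mt-Nd5 (0.58) and H2-T23 (-0.51) did not pass, while Ndufv1, Ndufa9, Uqcrc1, Atp5g3, Mylpf, Casq1, Rps28 and Rps3 stayed past the threshold. GC-corrected members higher and lower were 3 and 0 for fatty acid oxidation, 3 and 1 for biogenesis regulators, 4 and 2 for the AMPK pathway and 1 and 1 for CD47, thrombospondin and nitric oxide signalling. Among biogenesis regulators (adjusted p = 0.925) 6 rose and 2 fell of 24, and 6 and 2 when adjusted over the list alone. Gabpa had 2.22 (SE 0.27), Sirt1 2.18 (SE 0.34) and the coactivator Ppargc1a 1.44 (SE 0.26). Ppargc1a had 0.44 with adjusted p = 0.401 after the GC correction. In the AMPK pathway (adjusted p = 0.925) 5 rose and 2 fell of 24, and 6 and 3 when adjusted over the list alone. Cab39 had 1.59 (SE 0.23) and Stradb -1.04 (SE 0.19). In the list of CD47, thrombospondin and nitric oxide signalling (adjusted p = 0.424) 6 rose and 3 fell of 23, and 7 and 3 when adjusted over the list alone. The inducible synthase Nos2 had -1.51 (SE 0.38), and -1.10 with adjusted p = 0.0620 after the GC correction. Nos2 did not pass without CD47-KO library 3 (-1.18). Of the 10 lists called (2 higher, 8 lower, of 44), 0 passed with an estimated correlation and 8 kept their call after the GC correction, where the endothelial list had adjusted p = 0.252. With GC content and length it had 0.160 and antigen presentation 0.0872. The fry test called 2 (fasting, adjusted p = 0.0137, and fast fibre, 0.0365). With numbers 1 to 3 of exercise alone, adjusted p was 0.270 for complexes II to IV, 0.0701 for fasting and 0.0573 for endothelial, and with numbers 4 to 6 alone 0.103 for endothelial. The fasting list had adjusted p = 0.0525 without CD47-KO library 3. The endothelial list had 0.120, 0.103 and 0.0853 without CD47-KO library 3, exercise library 1 or exercise library 6. The count of genes was 1723 after the GC correction, of which 1150 kept their call and direction, and 2488 (1828 higher, 660 lower), 2292 (1554 and 738) and 2329 (1701 and 628) without CD47-KO library 1, 2 and 3. With only the groups compared it was 4782 (2985 and 1797).

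The design also asks whether CD47-KO and exercise moved the same genes, both against sedentary. Across the 17975 genes tested, which are not independent replicates, Pearson's r of the 2 log2 fold changes was 0.253, the covariance 0.206, and 56.3% had the same sign. Unchanged groups simulated against the same 6 sedentary libraries gave a mean r of 0.391 (range 0.360 to 0.415 in 20 simulations) and a mean covariance of 0.206, so that the observed covariance differed from it by -0.000381. The simulated spread, however, holds the difference between the sets of numbers, which is balanced in the real exercise and sedentary groups. The simulated values may thus be too high, and cannot show that shared controls account for the whole observed covariance. With the sedentary libraries split between the comparisons, the median r over 20 splits was 0.00611 (range -0.176 to 0.0708). By edgeR 0 genes passed in both comparisons in the same direction, since 0 passed for exercise (665 and 6025 at an unadjusted p under 0.05), limma-voom gave 0 and DESeq2 gave 3. Independent lists of the edgeR sizes share 0. The 3 genes of DESeq2 were Alb, Ahsg and Gm15879, all lower. Alb and Ahsg are serum protein genes with most of their counts in sedentary libraries 1, 2 and 5, which both comparisons share.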

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

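All tests of the trend with GC content and of Cd47 in this part were chosen after the result was seen, and the counts over other splits of the libraries were planned before. Of 98 groups of 6 libraries examined with Dixon's test for a value far from the others, 7 held such a value, where chance flags about 1 in 20 groups. Exercise library 2 had 12.3% of its counts in the 2 clone symbols (95% Wilson interval 12.24 to 12.26%, which covers counting error only), and sedentary library 6 had 18.2% in mitochondrially encoded genes (95% Wilson interval 18.17 to 18.19%). The mean log2-cpm of the slow fibre list was 2.96 in exercise library 3. Sedentary library 1 lay far from the other 5 for Gm15564 (0.131 CPM), Acads (69.4 CPM) and Tnnt1 (2203 CPM). Exercise library 1 held Serpina3k at 0.0658 CPM, where the other 5 had 0 counts.

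The fold changes of the libraries labelled CD47-KO against sedentary fell with transcript GC content. After the GC correction 1175 of 3719 genes kept their call and direction, which is above the bound set. The curve fitted on GC content therefore does not account for all calls. The correlation with GC content ran from -0.331 to -0.764 between length deciles, however, and a single curve cannot remove such a difference. GC content as the cause of the calls that stayed is thus not excluded. Gene length alone was excluded as the source of the trend with GC content, since the median correlation with GC content within length deciles was -0.642. The fold changes also rose with transcript length, with a Spearman correlation of 0.346, and of 0.181 to 0.363 within GC deciles. The share of low values at multiples of 4 was 8.08 percentage points lower in the highest of the 3 CD47-KO libraries than in the lowest of the other 12, so these libraries may have been made or counted apart, which cannot be told apart from the group. Loss of CD47 as the source was not tested and stays open.

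Cd47 did not pass the test in the libraries labelled CD47-KO. Its log2 fold change lay at percentile 5.80 of 500 genes of like GC content and level, above the bound of 5 set for a lower level hidden by the GC trend, so this explanation cannot be told apart from an unchanged level, although the GC-corrected value was -1.21. The median log2 fold change of these 500 genes was 0.99. A single mislabelled library as the cause was excluded, as the log2-cpm of the 3 spanned 0.0787, so that no pair of them was low beside 1 at the wild-type level. An exchange of 1 of them with 1 of the other 12 libraries was excluded too, as their span on the second component was 1.06% of their gap to the nearest other library. Since all 3 lay within the sedentary range of Cd47, these values do not show that the labels are right. The GC-corrected level was 43.4% of sedentary, and an altered allele that still gives counted reads could leave such a level, which the counts per gene cannot decide. Whether the label or the measured level is right therefore stays open.

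The counts of calls were compared with other splits of the same libraries. For CD47-KO against sedentary, 1 of 84 splits, the real one, reached its 3719 genes (highest other 1134, with sedentary libraries 4 to 6 as the group of 3), and against exercise 1 of 84 reached 3698 (highest other 1), so chance was excluded as the source of both counts. For lists it was not: 58 of 84 splits reached the 11 lists against sedentary (highest other 22) and 63 of 84 the 10 lists against exercise (highest other 23). For exercise against sedentary, 100 of 100 splits drawn of 462 reached 0 genes (highest other 5482, numbers 1 to 3 against 4 to 6), and 44 of 100 reached the 15 lists (highest other 21). Among the 32 ways to swap exercise and sedentary within numbers, with the number as a block, the real one gave 16 lists, 11 others gave as many and the highest gave 22, and the 4 drawn splits that part all 6 numbers gave at most 14. The number of exercise lists is thus no larger than other groupings of the libraries gave.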

How the results depend on the processing

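The corrections for GC content, the fits by sets of numbers and the fit without sedentary libraries 1 and 6 were chosen after seeing the data. Genes changed by exercise against sedentary numbered 9 with DESeq2 (2 higher, 7 lower) and 1 with the set as a block (Il15, 1.38), against 0. Genes of CD47-KO against sedentary numbered 1748 with the GC correction (850 higher, 898 lower), 1747 with GC content and length (872 and 875) and 5588 with numbers 1 to 3 alone, and 2178 to 3881 when 1 library was left out, against 3719. Against exercise they numbered 1723 (974 and 749) and 1974 (1093 and 881) with the corrections and 2292 to 3554 when 1 library was left out, against 3698. Cd47 in CD47-KO against sedentary passed with the GC correction (-1.21) and with GC content and length (-1.32), and was -0.32 to -0.15 when 1 library was left out. Against exercise Cd47 also passed as lower with both corrections. The correlation of the comparisons was 0.354 with numbers 4 to 6 alone and 0.210 to 0.328 when 1 library was left out, and genes shared by both numbered 3 with DESeq2 and 0 to 0 when 1 library was left out. The corrections change the values by construction, and otherwise the cause was not tested.

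Lists numbered 0 with an estimated correlation in each comparison, against 15, 11 and 10. They numbered 7 with numbers 4 to 6 alone for exercise, and 7 (3 higher, 4 lower) with GC content and length for CD47-KO against sedentary. Leaving out 1 library gave 11 to 18, 9 to 13 and 8 to 11 lists. Directions turned for mt-Nd6 (-0.11) and Ugp2 (-0.19) in CD47-KO against sedentary with the GC correction, and for Ugp2 (-0.14) with GC content and length. They also turned for Cd36 in exercise against sedentary (-0.13) and Cd47 in CD47-KO against exercise (0.0797) with numbers 1 to 3 alone, for Junb in exercise against sedentary (-0.62) with numbers 4 to 6 alone, and for Cd47 in exercise against sedentary (0.00363) without sedentary libraries 1 and 6.

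With the replicate number as a block the counts were 0, 4842 and 4980 genes and 16, 14 and 12 lists, the correlation 0.223 and Cd47 -0.16. Of named genes, Ckm (-0.80) and H2-T22 (-0.61) lost their calls against sedentary. Of lists, macrophage in exercise (adjusted p = 0.157), ATP synthase (0.0604), complexes II to IV (0.425) and glycolysis (0.0693) against sedentary and complexes II to IV against exercise (0.158) lost theirs. It ended no other call of a named gene or a list, and it added lists to each comparison. Of 79 genes named against sedentary, 53 of the 76 called stayed called with the GC correction. RLE factors moved the median log2 fold change by -0.03, 0.03 and 0.05. Depth limits which genes have counts enough to be tested, here 17975 of 22798 symbols. At this depth and group size edgeR recovered 30, 17 and 19 of 100 simulated genes with a log2 fold change of 1 in the 3 comparisons, and what limits the rest was not tested.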

Other observations

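The genes in this part and the tests of the clock genes were chosen after their values were seen. Of the heat shock and protein folding list, 8 rose and 0 fell of 25 in the libraries labelled CD47-KO against sedentary, or 3 and 0 after the GC correction, and the list did not pass (median -0.04, adjusted p = 0.306). The mitochondrial chaperonin Hspd1 had 1.25 (SE 0.18), GC-corrected 0.99, the co-chaperone Hspa4 1.11 (SE 0.19), GC-corrected 0.81 and Hsp90aa1 1.79 (SE 0.29), GC-corrected 1.08. The antioxidant list did not pass either (adjusted p = 0.624; 6 rose and 7 fell of 27, GC-corrected 3 and 1), with Nfe2l2, which drives the antioxidant response, at 1.36 (SE 0.19), GC-corrected 1.09, Gclc, for glutathione synthesis, at 1.05 (SE 0.16), GC-corrected 0.87, Hmox1 at 1.59 (SE 0.49), GC-corrected 1.91 and thioredoxin Txn1 at -0.84 (SE 0.22), GC-corrected -1.10. Of the insulin signalling list (adjusted p = 0.409; 5 rose and 1 fell of 24, GC-corrected 2 and 1), the receptor substrate Irs1 had 1.57 (SE 0.21), GC-corrected 1.68 and the kinase Pik3ca 2.12 (SE 0.22), GC-corrected 1.05. Of the lipid and cholesterol list (adjusted p = 0.734; 2 rose and 2 fell of 25, GC-corrected 1 and 1), the sterol sensor Insig1 had 1.82 (SE 0.29), GC-corrected 1.72 and Fdps, of isoprenoid synthesis, -0.97 (SE 0.15), GC-corrected -0.84. Hmox1 did not pass without sedentary library 1 (1.44), CD47-KO library 2 (1.27) or CD47-KO library 3 (1.69) and Txn1 without CD47-KO library 1 (-0.76) or CD47-KO library 2 (-0.81).

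The clock list did not pass in CD47-KO against sedentary (adjusted p = 0.358 by camera), where 3 of 21 members rose and 6 fell. Its 3 activators rose, while of 10 repressor and output genes 5 fell and 0 rose, or 4 and 0 after the GC correction. The activators had 1.65 (SE 0.35), GC-corrected 1.54 (Arntl), 2.29 (SE 0.38), GC-corrected 1.28 (Clock) and 2.33 (SE 0.39), GC-corrected 2.59 (Npas2). Among the others were the repressors Per2 (-2.02, SE 0.32, GC-corrected -1.63) and Bhlhe41 (-0.90, SE 0.22, GC-corrected -1.08) and the output gene Dbp (-2.98, SE 0.48, GC-corrected -2.38). The repressor gene Nr1d2 lay the other way (1.22, SE 0.43, GC-corrected 0.34) and did not pass. It did pass with the replicate number as a block, and against exercise it was 1.31 (adjusted p = 0.0397 by edgeR). Clock did not pass after correction for GC content and length. Bhlhe41 did not pass without CD47-KO library 2 (-0.75) or CD47-KO library 3 (-0.81). The median GC-corrected value of the repressor and output genes less that of the activators was -2.66, so a difference remained after the GC correction. Both groups of genes and the bound were chosen after the values were seen, and the correction may leave a part of the trend. GC content is therefore not excluded as a contributor. A different hour of collection is a hypothesis that may explain these clock changes. After the GC correction 8 of 10 repressor and output genes lay below 0, 4 of them past the threshold. No label gives an hour, however, and the hour cannot be told apart from the group. An effect of CD47 on the clock was not tested.

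The highest counts of 3 genes typical of liver were in sedentary libraries 1, 2 and 5, and where these transcripts came from was not tested. Alb had 734, 721, 4, 12, 322 and 10 counts in sedentary libraries 1 to 6, 0 in all exercise libraries and 0, 8 and 8 in the libraries labelled CD47-KO. Ahsg, for the serum protein fetuin-A, had 86, 118, 0, 19, 43 and 12 counts in sedentary libraries 1 to 6, 0 in all exercise libraries and 0, 4 and 0 in the libraries labelled CD47-KO. Serpina3k, of a liver protease inhibitor, had 104, 119, 4, 0, 62 and 8 counts in sedentary libraries 1 to 6, 4 in exercise library 1, 0 in the other 5 and 0, 8 and 11 in the libraries labelled CD47-KO. Il15, a muscle cytokine, had 1.45 (SE 0.38) in exercise against sedentary and was the 1 myokine that passed when adjusted over the list alone. Ddx3y, on chromosome Y, was measured in every library, at 4.36 to 21.7 CPM in sedentary, 5.13 to 15.6 in exercise and 85.0 to 109 in the libraries labelled CD47-KO (2.79, SE 0.38, GC-corrected 1.32). Uty, Kdm5d and Eif2s3y, also on chromosome Y, had 14.3 to 18.2, 13.1 to 16.4 and 53.2 to 58.6 CPM in the libraries labelled CD47-KO. Their highest levels in the other libraries were 4.84, 7.57 and 17.2 CPM. The source of these differences was not tested.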
